A study of Rattus norvegicus with 8 samples.

How the data were processed

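RNA of adipose-tissue-derived mesenchymal stem cells (ATSC) was profiled on 8 single-colour (Cy3) Agilent Whole Rat Genome arrays, 1 array per sample. The labels place 3 samples on liver after ischemia-reperfusion injury (IRI), 4 on liver without it (non-IRI) and 1 in culture (in vitro). They give each sample a replicate number but do not say that replicates are separate animals, so each p-value below measures the spread between these samples. Per the labels, RNA was extracted with TRIzol and labelled from 0.5 µg.

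Per the file headers, the scanner files hold the intensity of each spot as processed by Feature Extraction 11.0.1.1, background-subtracted and detrended within the array, with no scaling between arrays. Feature Extraction 9.1 is named instead per the submitters' processing notes. The deposited value table is in log2 units; its scale, centring and direction were settled by comparing it with the scanner signals. In that table the authors scaled log2 signals to each array's 75th percentile and then centred each probe on its median over the 8 arrays. The largest absolute probe median was 5e-07, and each column correlated with the centred scanner values, across probes, at r = 0.9997 or more. The column medians of the authors' table were 0.18, -0.07 and -0.05 for IRI 1 to 3, 0.16 for in vitro, and 0.09, -0.15, -0.02 and -0.02 for non-IRI 1 to 4. Of its 41105 probes, 41012 matched a non-control probe of the scanner files.

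Values were computed from the deposited scanner intensity as log2 of the processed signal minus the 75th percentile of the array's 43379 non-control spots. Between 45 and 117 spots per array that the scanner software marked as non-uniform or as outliers were left out, and no non-control spot was saturated. The 1639 control spots were not used here. Spots of 1 probe were averaged. A probe was kept if it was well above background on at least 3 of the 7 liver arrays or on the in vitro array, which left 24821 probes. Probes took their symbols from a table that pairs RefSeq transcripts with symbols: 17541 of 41012 probes had a symbol and 23471 did not. Each gene was represented by its kept probe with the highest mean log2 value. That gave 21309 genes, 9602 of them with a symbol; records without a symbol are called genes too. For 70 genes a value was missing on some array, and 11 had no in vitro value, which left 21298 for comparisons with culture.

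Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, no weights) on all 8 arrays. The residual degrees of freedom were 5 and the prior ones 2.81. The 4 comparisons were IRI minus non-IRI, the mean of both liver groups minus in vitro, IRI minus in vitro and non-IRI minus in vitro. The in vitro group holds 1 array and was assumed to vary like the liver arrays. P-values were adjusted by Benjamini and Hochberg's method over all genes tested, and a gene was said to rise or fall at an adjusted p under 0.05. Where no array of a group was well above background for a gene, its fold is a lower bound, written as "at least". It was computed with each array of that group at its lowest value well above background, or at its own value if higher.

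For 37 gene lists, fixed by name, camera tested whether a list's genes differed from all others, with a preset correlation of 0.01 between genes. Of these lists, 36 held at least 3 kept genes; camera was repeated with an estimated correlation, and fry was run. The list p-values were adjusted over the lists of a comparison. The lists cover 13 marker sets of cell types and related groups (hepatocyte, macrophage and Kupffer cell, neutrophil, T and NK cell, B cell, endothelial, erythroid, cholangiocyte, mesothelial, adipocyte, mesenchymal stromal, Y-linked, MHC class II). The others cover osteogenic and chondrogenic genes, collagens, proteases and their inhibitors, growth factors, cytokines and chemokines, and immune modulation. Stress and signalling lists cover hypoxia and glycolysis, oxidative stress, heat shock, the unfolded protein response, immediate early genes, cell cycle, apoptosis and p53, interferon, complement, acute phase, TGF-beta and fibrosis, adhesion and migration. The remaining lists are lipid and cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, drug and bile metabolism, and housekeeping genes.

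Named genes followed a rule. It took the 8 largest rises and 8 largest falls of IRI against non-IRI and of liver against culture among genes that passed, had a symbol and had no overlap between the arrays compared. It added up to 3 members with the smallest p from each described list, and Actb and Gapdh. Not every gene that the rule takes is named in the text. Groups, comparisons, tests, lists, the naming rule and most alternatives were set before the data were examined. The alternatives tried were other scalings, background correction, filters, probe rules, array weights, priors, the authors' table, a fold limit, a slide block, a replicate block and leaving out each liver array. Alternatives added after seeing the data are named with the results that depend on them.

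Replicate numbers were checked as possible pairs. After removing group means, IRI and non-IRI arrays of the same number correlated across genes at r = 0.188, 0.164 and 0.102 for numbers 1 to 3, and arrays of different numbers at -0.189 to 0.0821. The number was therefore tried as a block over the 7 liver arrays, although the labels do not say what it marks. No IRI array shares the number of non-IRI 4, so that array adds nothing to the difference in the fit with the block. Slides were inferred from the scan time in the file headers, not from a slide label. By that rule all 3 IRI arrays and the in vitro array lay on slide 1, and all 4 non-IRI arrays on slide 2. They were scanned at 426 and 427 volts. A slide term therefore could not be fitted for IRI against non-IRI or non-IRI against in vitro, where slide and group cannot be told apart.

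The pipeline was tested on simulated data with 21239 genes, 200 changed per run and 5 runs. For IRI against non-IRI it recovered 18.8% of 2-fold and 87.6% of 4-fold changes, with 37 false calls among 598. For liver against culture it recovered 69% of 4-fold and 96.8% of 16-fold changes, with 56 false calls among 909. A list of 30 genes shifted by 1 log2 unit was called by camera in 5 of 5 runs, and an unshifted list in 0, at an unadjusted p under 0.05. The simulated genes varied independently, so these runs do not test the preset correlation of 0.01. In the measured lists the estimated correlation ran from -0.22 (chondrogenic) to 0.88 (MHC class II). The number of arrays limits the precision, and no spike-in was used to set a common scale. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.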

Results

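Expression was measured in ATSC, stromal cells grown from fat taken under the skin of male rats (Sprague-Dawley), on 8 arrays. Of these, 3 hold ATSC on liver after ischemia-reperfusion injury (IRI, in which blood flow is stopped and then returns), 4 hold ATSC on liver without injury (non-IRI), and 1 holds cultured ATSC (in vitro). Between 53.5% of spots (in vitro) and 59.7% (non-IRI 3) were well above background, and the 75th percentile of the signal ran from 156 (IRI 1) to 291 (IRI 2) intensity units. All levels below are log2 values relative to that percentile of the array. Across genes, which are not independent replicates, Spearman's rho was 0.975 to 0.990 between IRI arrays, 0.966 to 0.982 between non-IRI arrays and 0.955 to 0.976 between the groups. The in vitro array correlated with IRI arrays at 0.848 to 0.856 and with non-IRI arrays at 0.840 to 0.854. Actb, a cytoskeletal gene, had a mean of 8.73 ± 0.14 (SD, n = 3) in IRI, 8.73 ± 0.16 (n = 4) in non-IRI and 9.24 in vitro. Gapdh, a glycolytic enzyme, had 7.26 ± 0.29, 7.12 ± 0.17 and 7.89.

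The first comparison sets ATSC on injured liver against ATSC on liver without injury. Genes that hepatocytes transcribe were higher on the IRI arrays. Of the 29 kept genes of the hepatocyte list, 17 rose, 0 fell and 12 did not pass; 28 were higher in IRI, with a median log2 difference of 2.94, and 21 rose adjusted over the list alone. The smallest p-values belonged to Hpx, which binds free heme, Apoh, a plasma glycoprotein, and Apoa1, the main apolipoprotein of high-density lipoprotein. Hpx rose by 1.94 (adjusted p = 0.0019), Apoh by at least 4.51-fold (0.00662) and Apoa1 by 2.94 (0.00889). The list mean was -0.28, -0.12 and -0.87 on IRI 1 to 3, -3.93, -3.19, -2.31 and -2.41 on non-IRI 1 to 4, and -4.44 in vitro. Camera gave an adjusted p of 1.2e-20, and the adjusted p = 0.397 with an estimated correlation. The list's direction and camera call held without each array, but the number of risen members was 6 without IRI 1, 3 without IRI 2, 5 without IRI 3 and 5 without non-IRI 2, and 5 with the replicate number as a block. It was 10 with only genes with a symbol tested, and 6 of 9 with probes well above background on all 8 arrays. Apoa1 did not pass without IRI 3 (adjusted p = 0.0504), and Apoh did not pass with the block (0.0579) or under normexp without bright background spots (0.0524). With background corrected by normexp, the list median was 1.18 without bright background spots, and 0.63 with them, where 0 members passed. The setting without bright background spots kept those spots and set their background to the array's median. Normexp here added an offset of 50 to the signals, which shrinks log2 differences of dim genes.

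**Figure D1:**
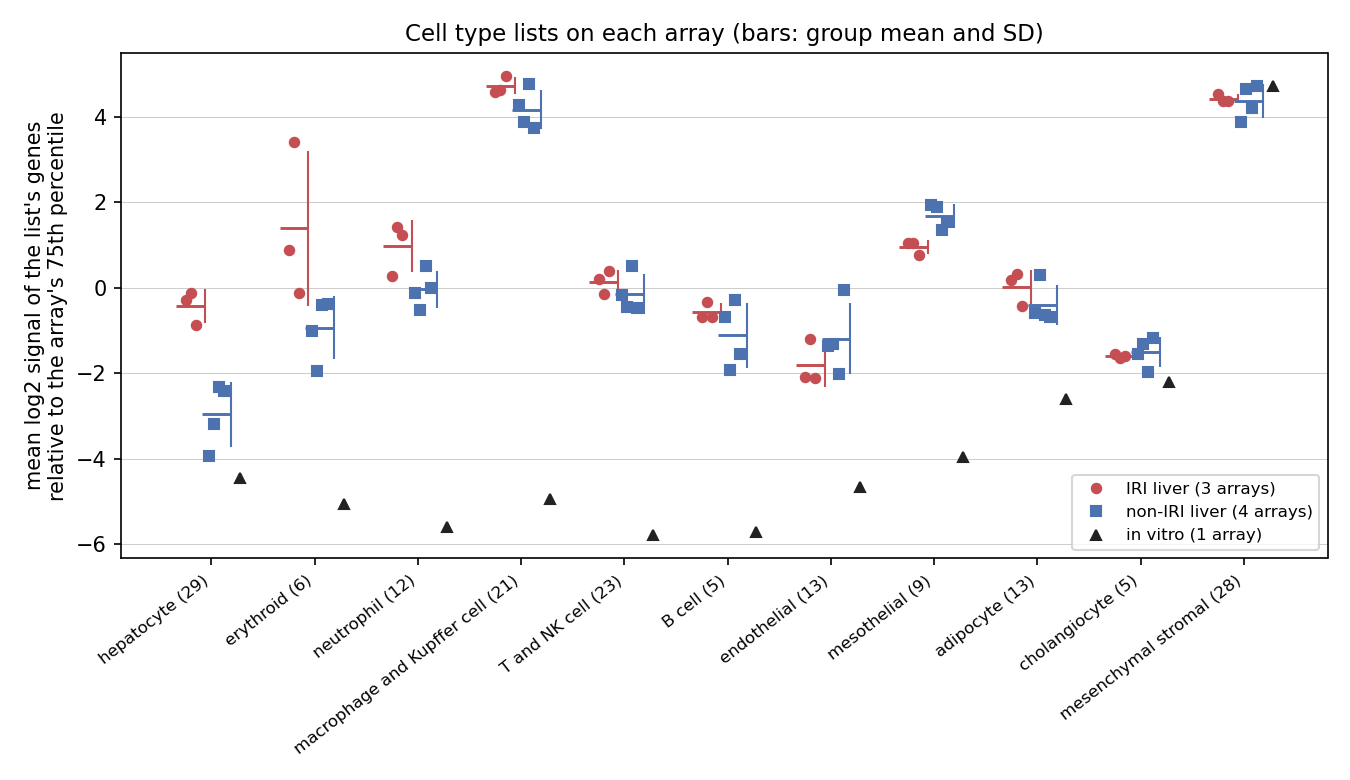
Each point is the mean log2 signal, relative to the array's 75th percentile, of a cell type list's kept genes (number in brackets) on 1 array of the IRI, non-IRI or in vitro group, with bars for group mean and SD. The hepatocyte list lies at -0.87 or above on all 3 IRI arrays and at -2.31 or below on all 4 non-IRI arrays, and the mesenchymal stromal list lies at a like level in all groups.

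Of the 8 largest rises, Kng1, Ahsg, Fga, Fgb and Itih4 belonged to the hepatocyte list. Kng2 (NM_012696) and Kng1 (NM_001009628) encode kininogens, the plasma precursors of bradykinin. Kng2 rose from -4.16 ± 1.31 (SD, n = 4) in non-IRI to 0.31 ± 0.82 (n = 3) in IRI, a log2 difference of 4.47 ± 0.71 (SE; adjusted p = 0.0155), and Kng1 rose by 4.25 ± 0.77 (0.0279). Ahsg (NM_012898), which encodes fetuin-A, rose from -4.67 ± 1.32 to -0.52 ± 0.13, by 4.15 ± 0.64 (0.0141). The fibrinogen chain genes Fga and Fgb rose by 3.73 ± 0.69 (0.0292) and 3.69 ± 0.60 (0.0174), and Fgb reached 2.72 ± 0.21 in IRI. Apoa4, an apolipoprotein, rose by 3.93 ± 0.81 (0.0476), Itih4, an inhibitor heavy chain of plasma, by 3.70 ± 0.72 (0.037), and Sult2a6, a sulfotransferase, by at least 5.19-fold (0.0106). With the replicate block, Kng2 and Ahsg passed and the other 6 did not: Kng1 0.0637, Apoa4 0.151, Sult2a6 0.109, Fga 0.0502, Itih4 0.0732 and Fgb 0.0724. Kng1, Ahsg, Apoa4 and Itih4 were well above background on at most 2 of the 4 non-IRI arrays. The sizes of these rises therefore rest partly on values not well above background. Each of the 8 lost its call without at least 1 array. Without IRI 2 the adjusted p was 0.0690 for Kng2, 0.114 for Kng1, 0.0632 for Ahsg, 0.175 for Apoa4, 0.0505 for Sult2a6, 0.119 for Fga, 0.143 for Itih4 and 0.0773 for Fgb. Without IRI 3 it was 0.0752, 0.121, 0.0685 and 0.0814 for Kng2, Kng1, Ahsg and Apoa4, and 0.130, 0.112 and 0.0768 for Fga, Itih4 and Fgb. Without IRI 1 it was 0.111 for Apoa4, 0.0520 for Fga, 0.0838 for Itih4 and 0.0507 for Fgb. Without non-IRI 2 it was 0.0556, 0.0862, 0.0511 and 0.0941 for Kng2, Kng1, Ahsg and Apoa4, and 0.0879, 0.0930 and 0.0574 for Fga, Itih4 and Fgb. Without non-IRI 1 it was 0.116 for Apoa4 and 0.0667 for Itih4, and without non-IRI 4 it was 0.0713 for Kng1, 0.0608 for Apoa4 and 0.0578 for Fga.

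Acute phase genes, which the liver makes in inflammation, were higher in IRI along with the hepatocyte list (median 2.94). Of 21 kept, 9 rose, 0 fell and 12 did not pass, with a median of 1.29; adjusted over the list alone 12 rose and 2 fell, and 5 members are also in the hepatocyte list. Orm1, which encodes orosomucoid, rose by at least 2.73-fold (adjusted p = 0.00136), and Lcn2, an iron-siderophore binding protein, rose from 1.44 ± 0.24 (SD, n = 4) to 3.19 ± 0.48 (n = 3), by 1.75 ± 0.25 (SE; 0.0111). Itih3 rose by 2.52 (0.0125). Camera gave 1.4e-07 for the list, and the adjusted p = 0.397 with an estimated correlation. The replicate block left 2 risen members, with Lcn2 at 0.0728 and Itih3 at 0.102. The median was 0.83 without IRI 2 and 0.50 with probes well above background on all 8 arrays, where 3 rose and 1 fell. It was 0.68 under normexp without bright background spots and 0.62 with them, where 0 rose, and 5 rose with only genes with a symbol tested. Leaving out 1 array left 3 without each of IRI 1, IRI 2 and IRI 3, 6 without non-IRI 1 and 5 without non-IRI 2; Lcn2 did not pass without IRI 3 (0.0650), nor Itih3 without IRI 2 (0.0556). Orm1 also did not pass under normexp, with bright background spots (log2 difference -0.081, adjusted p = 0.94) or without them (0.55, 0.196).

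Drug and bile metabolism genes, a further set of hepatocyte functions, shifted the same way: of 16 kept, 2 rose, 0 fell and 14 did not pass, with a median of 0.61 and 5 risen adjusted over the list alone. Gsta2, a glutathione transferase, rose by at least 6.19-fold (adjusted p = 0.00141), although its in vitro level was 0.87 against -1.99 in IRI. Cyp2c6v1, a cytochrome P450, rose by 2.76 (0.034), and Adh1c, an alcohol dehydrogenase, was higher by 2.27 (0.0886). Camera gave 2.66e-04 for the list, and the adjusted p = 0.404 with an estimated correlation. Cyp2c6v1 did not pass with the replicate block (0.125), under normexp without bright background spots (0.0883), or without IRI 1 (0.0918), IRI 2 (0.129), IRI 3 (0.0772) or non-IRI 2 (0.0985). Under normexp with those spots the list's median was -0.02, and 8 of 16 members were higher. With probes well above background on all 8 arrays, the list call was lost (0.0592), and under normexp without bright background spots the median was 0.25.

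Blood cell markers had positive medians in IRI, while no single member passed, beside the hepatocyte list's 2.94. For the 12 neutrophil genes the median was 0.66 (11 higher, camera adjusted p = 2.69e-04; adjusted p = 0.548 with an estimated correlation), and 5 rose adjusted over the list alone. S100a9 and S100a8, the subunits of calprotectin, were higher by 2.74 (0.061) and 2.62 (0.0756), and Il1r2, a decoy receptor for interleukin-1, by 1.84 (0.0536). All 6 erythroid genes were higher, with a median of 2.70 (camera 9.4e-04; adjusted p = 0.558 with an estimated correlation): Alas2, of heme synthesis, by 3.06 (0.149), Hbb by 2.88 (0.222) and Ahsp, a chaperone of alpha globin, by 2.51 (0.245). The erythroid list mean was 3.41 on IRI 2, 0.90 on IRI 1, -0.11 on IRI 3 and -1.95 to -0.38 on the non-IRI arrays, and the median was 1.50 without IRI 2. The macrophage and Kupffer cell list had 16 of 21 genes higher and a median of 0.32 (camera 0.0129; adjusted p = 0.963 with an estimated correlation). Clec4f, a Kupffer cell lectin, was higher by 2.31 (0.0766), Marco by 2.36 (0.136) and Cd163 by 2.01 (0.219). For the 23 T and NK cell genes the median was 0.32 (21 higher, camera 0.0331; adjusted p = 0.968 with an estimated correlation), with Gzmk at 0.57, Il2rb at 0.48 and Cd4 at 0.79. With the replicate block, the macrophage (0.0533) and T and NK cell (0.0662) calls were lost; the macrophage call held in 4 of the 7 fits without 1 array (highest adjusted p 0.108, without non-IRI 4) and the T and NK cell call in 3 (highest 0.305, without IRI 3). With probes well above background on all 8 arrays, these 2 calls were also lost (0.621 and 0.791). The macrophage median was 0.54 without IRI 1, 0.51 under normexp and 0.21 with probes well above background on all 8 arrays. The T and NK cell median was 0.10 without IRI 3, 0.53 without non-IRI 3, 0.17 under normexp without bright background spots, and 0.18 with the replicate block and with probes well above background on all 8 arrays. Median scaling took S100a9 (0.0361) and S100a8 (0.0482) past the test, and normexp without bright background spots took S100a9 (0.0201), S100a8 (0.0215), Il1r2 (0.0184) and Clec4f (0.0468).

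Genes of the mesothelial list, taken as markers of the lining of liver and abdominal cavity, were lower in IRI. Of 9 kept genes, 8 had negative differences, 0 rose, 1 fell and 8 did not pass, and 1 is also in the cholangiocyte list. The mesothelial list had a median of -0.74 and 3 falls adjusted over the list alone. Its median was -0.46 under normexp without bright background spots. The hepatocyte median was 2.94 and the erythroid median 2.70 in the same comparison. Gpm6a, a membrane glycoprotein, changed by -1.74 (adjusted p = 0.0464), while Bnc1 differed by -1.58 (0.0599) and Upk1b by -0.99 (0.112). Camera gave 0.00443 for the list, and the adjusted p = 0.548 with an estimated correlation. Gpm6a did not pass with the replicate block (0.0775), where Bnc1 did (0.0417). Bnc1 also passed with median scaling (0.0474), and under normexp without bright background spots so did Bnc1 (0.0440) and Upk1b (0.0415). Gpm6a also did not pass under that normexp setting (0.124), or without IRI 1 (0.0569), IRI 2 (0.167), IRI 3 (0.206), non-IRI 1 (0.118), non-IRI 2 (0.117) or non-IRI 4 (0.123).

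The mesenchymal stromal list, whose genes mark stromal cells such as ATSC, did not pass: of 28 kept genes 0 rose and 0 fell, with a median of 0.04 (camera 0.932). The labels name no sort, so the signal of this list on the liver arrays cannot be assigned to ATSC alone. The smallest p-values there belonged to Thy1, which differed by -1.05, Alcam by -0.50 and Ly6al by -0.69. The other cell type lists had medians of 0.41 for B cells (5 genes, 0.157), -0.56 for endothelium (13 genes, 0.312), 0.01 for cholangiocytes (5 genes, 0.932), 0.25 for adipocytes (13 genes, 0.157) and -0.34 for MHC class II (7 genes, 0.0965), with 0 members past the test in each. Among their members, Cd22 differed by 1.05, Blnk by 0.41, Fcrla by 0.39, Kdr by -0.75, Cldn5 by -2.27, Krt19 by -0.74, Slc4a2 by 0.18 and Prom1 by 0.10. Retn differed by 1.82, Dgat2 by 0.80, Pnpla2 by 1.00, RT1-Bb by -1.40, Ciita by -0.85 and RT1-Da by -0.34, and Sox17 by -2.07 (adjusted p = 0.13; 0.0495 with the replicate block). The endothelial list mean was -0.05 on non-IRI 4 and -2.02 to -1.32 on the other non-IRI arrays, and without non-IRI 4 the list's median was -0.04 (0.874). The MHC class II list passed with the replicate block (0.0131), with quantile normalization (0.0498), with median scaling (0.0439) and under normexp without bright background spots (0.0255), where Retn passed too (0.0481). Under normexp with those spots, the mesenchymal stromal list passed, with a median of 0.40 (6.16e-05).

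Besides acute phase and drug metabolism, 4 response lists passed camera with small shifts, in the comparison where the hepatocyte median was 2.94. Immune modulation had 17 genes and a median of 0.46 (14 higher; camera 0.0129; adjusted p = 0.548 with an estimated correlation), with 3 rises and 1 fall adjusted over the list alone. Cd200, a ligand that restrains macrophages, fell there by 1.37 (adjusted p = 0.0396), while Nos2, the inducible nitric oxide synthase, was higher by 2.94 (0.0562) and Hmox1, heme oxygenase, by 1.09 (0.141). The Cd200 call was lost with the replicate block (0.0531) and without IRI 1 (0.0548), IRI 2 (0.104), IRI 3 (0.153), non-IRI 1 (0.114), non-IRI 2 (0.103) or non-IRI 4 (0.110). Oxidative stress (30 genes, 24 higher) had a median of 0.17 (camera 0.0115; adjusted p = 0.404 with an estimated correlation), with Gsr at 0.70 and Nqo1 at 0.67. Hypoxia and glycolysis (33 genes, 26 higher) had 0.26 (camera 0.0331; adjusted p = 0.968 with an estimated correlation), with Hk1 at -0.54, Pfkfb4 at 0.85 and Gpi at 0.46. Another kept probe of Hk1 differed by 0.38. The unfolded protein response (21 genes, 18 higher) had 0.18 (camera 0.0475; adjusted p = 0.963 with an estimated correlation), with Calr at 0.48, Creld2 at 0.75 and Dnajb11 at 0.64. Without 1 array the hypoxia median ran from 0.11 (non-IRI 1) to 0.46 (IRI 1), and the unfolded protein median was 0.058 without IRI 2 and 0.098 without non-IRI 1. Under normexp with bright background spots the hypoxia, unfolded protein and oxidative stress medians were 0.45, 0.45 and 0.33. In the last 3 lists 0 genes passed, and with the replicate block 1 hypoxia gene rose. With array weights, 4 oxidative stress, 3 hypoxia and 2 unfolded protein genes rose. Leaving out IRI 1 gave 1 oxidative stress rise. The unfolded protein call was lost with the replicate block (0.0719), with probes well above background on all 8 arrays (0.0592), with median scaling (0.0767), with the authors' table (0.0521) and in 4 of 7 fits without 1 array (highest 0.407, without IRI 2). The hypoxia call was lost in 4 of those fits (highest 0.678, without IRI 2), the immune modulation call in 2 (highest 0.0972, without IRI 2) and the oxidative stress call in 1 (0.0732, without non-IRI 1). Normexp without bright background spots also ended the oxidative stress (median 0.11, 0.0626) and hypoxia (0.0674) calls.

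**Figure D2:**
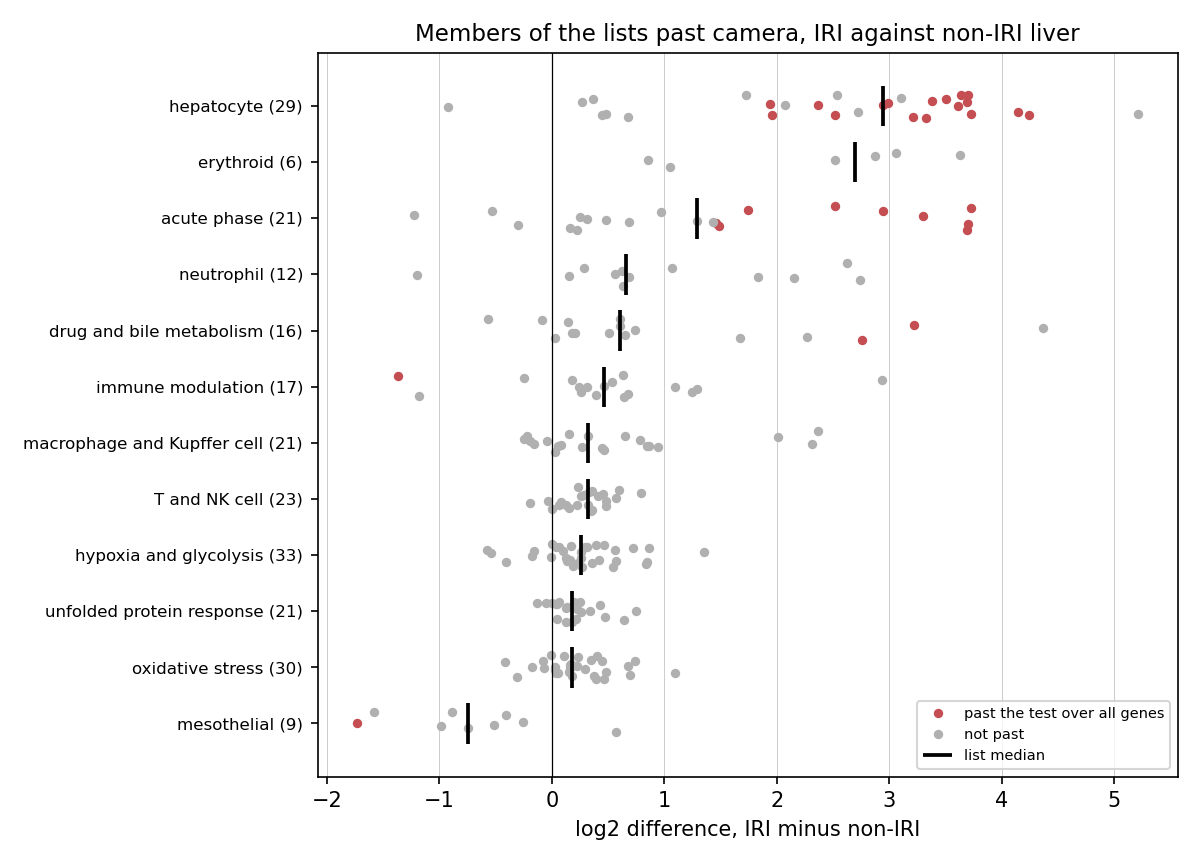
Log2 difference of IRI minus non-IRI (horizontal axis) for each kept gene of the 12 lists past camera, with the list median as a bar and genes past the test over all genes in red. The hepatocyte list has 17 red points, the acute phase list 9, and 7 lists have none.

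Of the 99 fallen genes with a symbol, 3 were in any list. Lactb (NM_001106833), a mitochondrial serine beta-lactamase-like protein, fell from -1.42 ± 0.18 (SD, n = 4) in non-IRI to -5.05 ± 0.47 (n = 3) in IRI, a log2 difference of -3.63 ± 0.24 (SE; adjusted p = 0.00136). Prph (NM_012633), the intermediate filament protein peripherin, fell from 3.16 ± 0.56 to -0.23 ± 0.23, by -3.40 ± 0.31 (0.00175), with 2.36 in vitro. Tmem106a fell by 3.40 (0.00137), Pecr, a peroxisomal reductase, by 3.28 (0.00136) and Aoc1, which degrades diamines, by 3.39 (0.0106; 0.0502 with the replicate block). Spint2, a protease inhibitor, fell by at least 7.75-fold (0.00136), Frem3 by at least 5.02-fold (0.00264) and Cox7c, a subunit of cytochrome oxidase, by at least 3.01-fold (0.00137). These 8 calls held in all 7 fits without 1 array, and under normexp without bright background spots Frem3 (0.141) and Cox7c (0.225) did not pass. Each call rests on 1 probe per gene. In culture only Prph and Pecr of the 8 were well above background. In IRI, Lactb and Pecr were so on 1 of 3 arrays, Tmem106a on 2, and Frem3, Spint2 and Cox7c on 0. The oxidative phosphorylation list, in contrast to Cox7c, had a mean of 4.45 in IRI and 5.04 in vitro. Whether the Cox7c probe reads its message was not tested. Where fallen genes with a symbol had other kept probes, these 13 probes of 12 genes had a median of -0.0043 against -1.35 for the probe used. Of the 13 probes, 4 lay far enough above the floor to show a fall of that gene's size. These 4 had a median of 0.31 against -1.16 for the probes used, and 1 of them was lower in IRI.

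In total 76 genes rose, 59 of them with a symbol, and 561 fell, 99 with a symbol; 82.4% of the falls were records without a symbol, against 54.9% of the genes tested. At an unadjusted p under 0.05 there were 3184 genes. The arrays did not overlap between the groups for 15.8% of genes, where chance gives 5.71%. With the replicate block 19 rose and 209 fell. The counts without 1 array were 83 and 605 without IRI 1, 23 and 321 without IRI 2, 21 and 256 without IRI 3, 48 and 372 without non-IRI 1, 36 and 403 without non-IRI 2, 86 and 461 without non-IRI 3, and 42 and 374 without non-IRI 4. All IRI arrays lay on 1 slide and all non-IRI arrays on another, so slide and group cannot be told apart in these counts and lists.

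Lists without a camera call for IRI against non-IRI are given with their median and camera's adjusted p. These were complement (0.19, 0.131), cytokines and chemokines (0.12, 0.0965), heat shock (0.14, 0.157), osteogenic (-0.12, 0.932) and chondrogenic genes (0.06, 0.932). Collagens (0.05, 0.667), proteases and inhibitors (0.05, 0.888), growth factors (-0.03, 0.888), immediate early genes (-0.11, 0.888) and cell cycle (0.05, 0.888) followed. Apoptosis and p53 had -0.05 (0.932), interferon -0.01 (0.888), TGF-beta and fibrosis -0.04 (0.888), and adhesion and migration 0.07 (0.863). Lipid and cholesterol synthesis had 0.02 (0.932), oxidative phosphorylation -0.07 (0.518), ribosomal proteins -0.01 (0.955) and housekeeping genes 0.03 (0.888). Without 1 array, cytokines and chemokines passed in 3 of 7 fits (lowest adjusted p 0.0209), MHC class II in 2 (0.00836), and complement (0.0218), heat shock (0.0492), ribosomal proteins (0.00613), B cells (0.0352) and adipocytes (0.0265) in 1 each. The test and the median had opposite signs for cholangiocyte, chondrogenic, apoptosis and p53, and TGF-beta lists. Only C3 in complement and Egr2 among immediate early genes passed, and both are named because of their values: C3 rose by 1.48 (adjusted p = 0.047) and Egr2, a growth-induced transcription factor, fell by 1.29 (0.0209). Egr2 did not pass with the replicate block (0.113), nor without IRI 2 (0.0845), IRI 3 (0.0868), non-IRI 1 (0.0644), non-IRI 2 (0.0570) or non-IRI 3 (0.0517). C3 did not pass without IRI 1 (0.102), IRI 3 (0.194), non-IRI 1 (0.0614), non-IRI 2 (0.0845), non-IRI 3 (0.0947) or non-IRI 4 (0.100). Y-linked genes were represented by Ddx3y (-0.18) and Eif2s3y (-0.66), neither past the test, and were too few for camera.

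The second comparison sets ATSC on liver, injured or not, against cultured ATSC. Of the 21 kept macrophage genes, 15 were not well above background in culture. The largest rises were Lyz2, the lysozyme of macrophages, at least 8180-fold (adjusted p = 3.49e-07), Cd74, the MHC class II invariant chain, at least 6199-fold, RT1-Da, a class II chain, at least 4676-fold, and C1qa, of complement C1q, at least 4458-fold. Lyz2 stood at 8.55 ± 0.24 (SD, n = 3) in IRI, 8.59 ± 0.30 (n = 4) in non-IRI and was not well above background in vitro. Aif1, a macrophage marker, rose at least 3279-fold, Ctss, a lysosomal protease, at least 1842-fold, Hbb-b1, a beta globin, at least 1388-fold, and Clec10a, a lectin of macrophages and dendritic cells, at least 928-fold.

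Macrophage and Kupffer cell genes rose in 20 of 21 cases, with 0 falls and 1 not past the test, and a median of 9.72, or 8.66 with undetected values at the floor (camera 2.1e-23; adjusted p = 0.178 with an estimated correlation). Tyrobp, a signalling adaptor, rose by 11.73. All 7 MHC class II genes rose (median 10.93, or 9.77 at the floor; camera 6.1e-09; adjusted p = 0.178 with an estimated correlation), RT1-Db1 by 10.93. Of 23 T and NK cell genes 22 rose (median 5.88, or 5.53 at the floor; 2.7e-17; adjusted p = 0.178 with an estimated correlation), among them Ccl5, a chemokine (at least 311-fold), Prf1, perforin (at least 97.5-fold), and Klrd1 (at least 50.3-fold). Of 12 neutrophil genes 9 rose (median 6.32, or 4.15 at the floor; 2.95e-08; adjusted p = 0.178 with an estimated correlation), among them Ncf4 and Ncf1, of the NADPH oxidase (at least 844-fold and 290-fold), and Fcnb (at least 136-fold). Of 5 B cell genes 4 rose (median 4.73, or 3.59 at the floor; 2.39e-04; adjusted p = 0.19 with an estimated correlation), among them Cd22 (at least 54.4-fold), Pou2af1 (at least 8.34-fold) and Blnk (5.50 on the log2 scale). The counts adjusted over the list alone were 20, 7, 22, 10 and 4.

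All 9 mesothelial genes rose (median 5.06, or 3.83 at the floor; camera 6.1e-09; adjusted p = 0.178 with an estimated correlation), with Krt18 at least 495-fold, Cdh1, E-cadherin, at least 16.6-fold, and Msln, mesothelin, by 4.86. Of 13 endothelial genes 5 rose and 0 fell (median 3.05, or 0.87 at the floor; 2.39e-04; adjusted p = 0.281 with an estimated correlation), among them Lyve1 of sinusoids and lymphatics (at least 232-fold), Esam (at least 44.1-fold) and Tie1 (at least 5.22-fold). Of 6 erythroid genes 3 rose (median 4.81, or 3.19 at the floor; 0.00874; adjusted p = 0.429 with an estimated correlation): Hbb-b1, Alas2 (at least 61.5-fold) and Hbb (at least 21.6-fold). Of 29 hepatocyte genes 17 rose, 1 fell and 11 did not pass (median 2.53, or 2.04 at the floor; 9.5e-07; adjusted p = 0.287 with an estimated correlation), with Tf, transferrin, at 9.67, Bhmt at 2.10 and Itih3 at least 9.40-fold. Of 13 adipocyte genes 4 rose and 1 fell (median 1.38, or 1.28 at the floor; 0.046, and 0.0616 without IRI 2; adjusted p = 0.178 with an estimated correlation), with Cd36, a fatty acid transporter, at least 64.8-fold, Cfd, adipsin, by 8.61 and Scd, a desaturase, changed by -5.86. That call ended with quantile normalization (0.0540), and with probes well above background on all 8 arrays the median was -0.15. Cholangiocyte genes divided 2 and 2 of 5 (median 0.67, 0.352): Krt19 rose at least 11.6-fold, Ggt1 at least 4.13-fold, and the water channel Aqp1 fell by 4.22. Under normexp without bright background spots Tie1 (0.117), Hbb (0.148) and Ggt1 (0.363) did not pass. The mesenchymal stromal list had 28 kept genes, 1 rise, 5 falls and a median of -0.36 (0.385), with Tagln, a smooth muscle actin-binding protein, changed by -1.86, S100a4 by -1.44 and Itgb1 by -1.40. Y-linked Ddx3y differed by -1.01 (0.124) and Eif2s3y by -0.63 (0.343).

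Immune response lists moved with the macrophage list, whose median was 9.72. In complement 16 of 22 genes rose and 1 fell (median 4.32, or 3.61 at the floor; camera 6.2e-11; adjusted p = 0.178 with an estimated correlation), with C1qb at 10.60 and C5ar1 at least 557-fold. Of 33 cytokine and chemokine genes 20 rose and 3 fell (median 3.40, or 1.93 at the floor; 9.5e-07; adjusted p = 0.178 with an estimated correlation), with Pf4 at least 733-fold and Il18 at least 165-fold. Of 34 interferon genes 26 rose and 2 fell (median 2.20, or 1.58 at the floor; 5.4e-10; adjusted p = 0.178 with an estimated correlation), with Cxcl10 at least 48.6-fold, Bst2 at 4.95 and Mx1 at least 4.94-fold (0.0634 under normexp without bright background spots). Of 21 acute phase genes 14 rose (median 3.30, or 3.00 at the floor; 1.8e-07; adjusted p = 0.178 with an estimated correlation), with Lcn2 at least 89.6-fold, A2m at 6.47 and C3 at 6.86. Of 24 adhesion and migration genes 7 rose and 1 fell (median 0.34, or 0.15 at the floor; 0.0101; adjusted p = 0.19 with an estimated correlation), the leukocyte genes Itgb2 (at least 355-fold) and Ccr2 (at least 20.1-fold) among the rises. With probes well above background on all 8 arrays, the cytokine list (median -0.30, adjusted p = 0.977), the adhesion list (-0.27, 0.810) and the endothelial list (3.35, 0.141) did not pass.

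**Figure D3:**
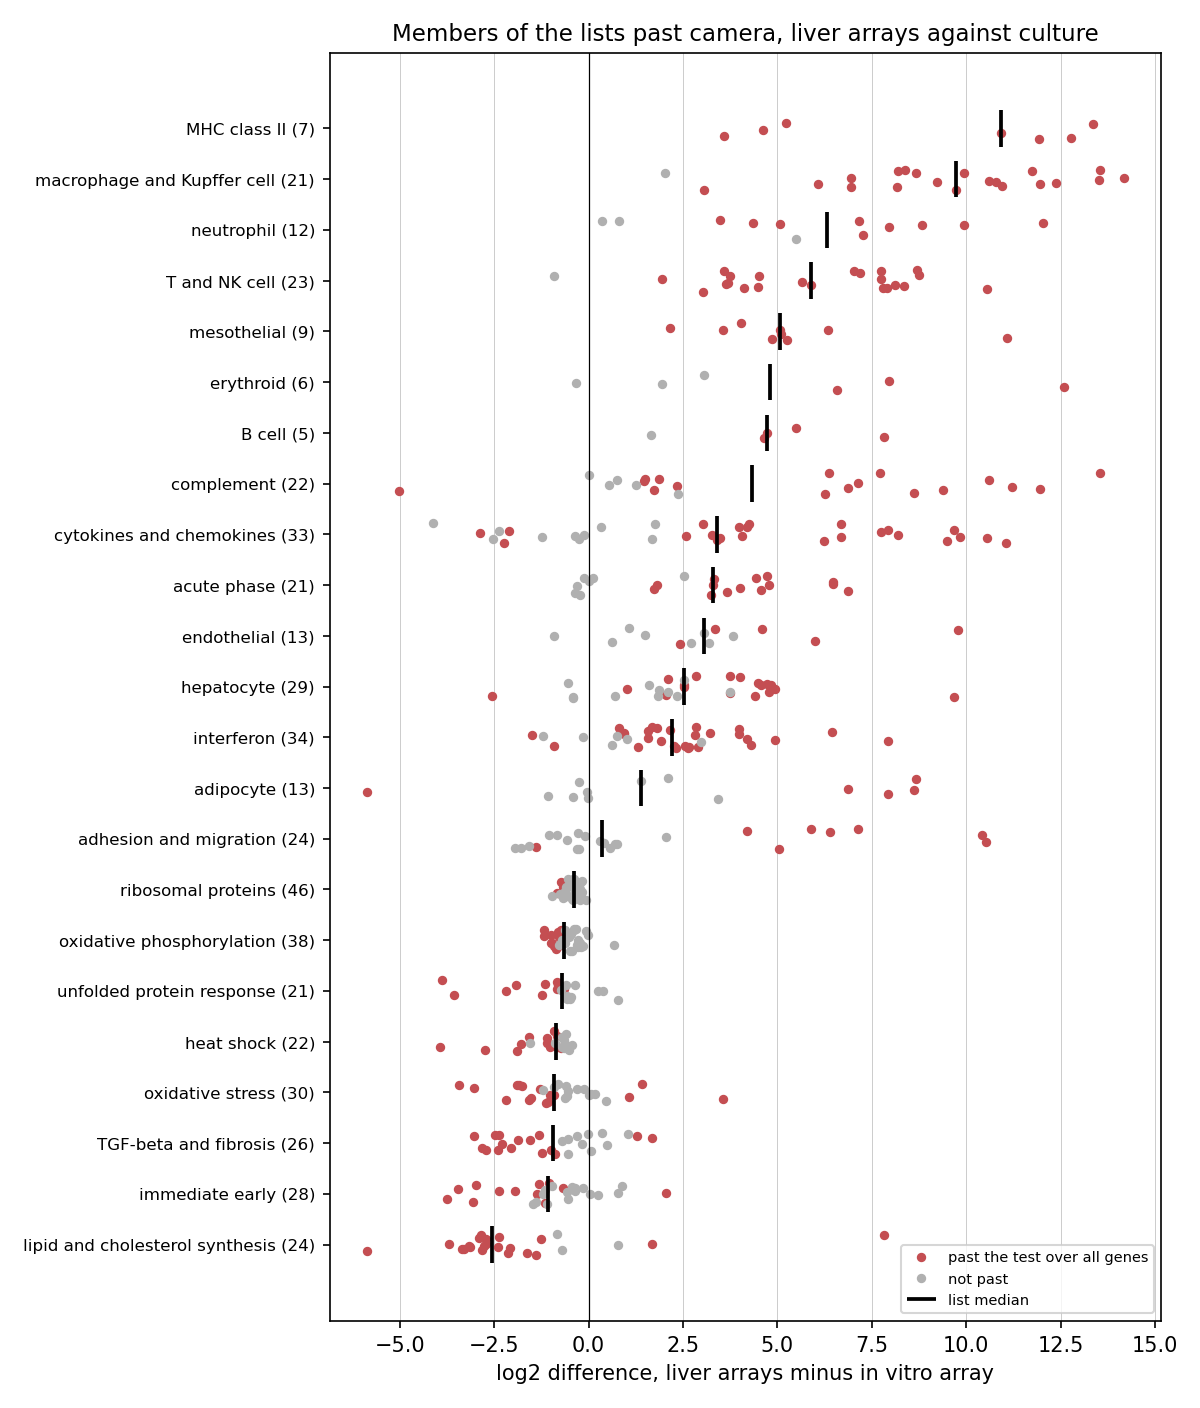
Log2 difference of the liver arrays minus the in vitro array (horizontal axis) for each kept gene of the 23 lists past camera, with the list median as a bar and genes past the test over all genes in red; undetected values are drawn as measured, not at the floor. The MHC class II and macrophage lists lie furthest to the right, with medians of 10.93 and 9.72, and the lipid and cholesterol list furthest to the left, at -2.55; the ribosomal list changed sign with quantile normalization.

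Genes higher in culture were led by Or4n5, an olfactory receptor (at least 17.0-fold, adjusted p = 1.21e-05), Hspb7, a small heat shock protein (at least 38.6-fold), and Scd (-5.86 ± 0.38 SE, 2.77e-05). Cntn2 fell by 5.27, Gja5, a connexin, by 5.22 (0.0263), Prl8a9 by 5.12, and Cd55, which inhibits complement, by 5.02. The lists that follow were lower in the comparison where the macrophage median was 9.72 and the MHC class II median 10.93. Lipid and cholesterol synthesis had the lowest median of the lists: of 24 genes 19 fell and 2 rose (median -2.55; camera 6.2e-07; adjusted p = 0.178 with an estimated correlation), with Dhcr7 at -2.77 and the exporter Abcg1 at 7.82. Of 22 heat shock genes 12 fell and 0 rose (median -0.86; 5.9e-05; adjusted p = 0.178 with an estimated correlation), with Cryab at -3.93, Hspb1 at -2.74 and Hspa1l at -1.90. Of 30 oxidative stress genes 13 fell and 3 rose (median -0.92; 0.00576; adjusted p = 0.178 with an estimated correlation), with Nqo1 at -3.44 and Prdx6 at -1.89. Of 21 unfolded protein genes 11 fell (median -0.71; 0.00395; adjusted p = 0.435 with an estimated correlation), with Chac1 at -3.88, Asns at -3.57 and Atf4 at -1.23. Of 26 TGF-beta and fibrosis genes 14 fell and 2 rose (median -0.94; 0.0101; adjusted p = 0.178 with an estimated correlation), with Ccn2 at -2.73, Ltbp2 at -2.49 and Tpm2 at -1.56. Of 28 immediate early genes 11 fell and 1 rose (median -1.07; 0.00874; adjusted p = 0.51 with an estimated correlation), with Dusp1 at -3.47, Klf4 at -2.36 and Myc at -1.95.

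Oxidative phosphorylation and ribosomal proteins shifted by less than 1 log2 unit, in the comparison where the macrophage median was 9.72. Of 38 oxidative phosphorylation genes 14 fell and 0 rose (median -0.64; camera 8.6e-04; adjusted p = 0.429 with an estimated correlation), with Ndufv1 at -1.17 and Ndufb8 at -0.92, and Ndufs3 among the falls. Of 46 ribosomal genes 5 fell (median -0.39; 0.01; adjusted p = 0.655 with an estimated correlation), with Rps10 at -0.83, Rpl28 at -0.73 and Rplp0 at -0.69; adjusted over the list alone 0 fell. The median of all genes was itself -0.25, and that of the 14 housekeeping genes was -0.53. Under quantile normalization the ribosomal median turned to 0.050 (0.51), the oxidative phosphorylation list had -0.26 (0.353), and Ndufs3 (0.0790), Ndufb8 (0.0751), Rps10 (0.161), Rpl28 (0.254) and Rplp0 (0.348) did not pass. Quantile normalization also ended the calls of oxidative stress (0.0540), the unfolded protein response (0.0540) and TGF-beta and fibrosis (0.0558).

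Lists without a camera call in this comparison were growth factors (median -1.10, 0.17, with 7 rises and 18 falls), apoptosis and p53 (-0.44, 0.803, 7 and 9), proteases and inhibitors (0.62, 0.17, 5 and 3) and hypoxia and glycolysis (0.52, 0.0516, 6 and 1). The hypoxia list passed camera in 3 of the 7 fits without 1 array (lowest adjusted p 0.00866). Immune modulation (0.18, 0.251) had 4 rises and 2 falls, drug and bile metabolism (-0.06, 0.749) 5 and 4, and collagens (-0.15, 0.803) 2 and 1. Osteogenic (0.08, 0.575) and chondrogenic genes (0.04, 0.575) and cell cycle (-0.28, 0.581) had 1 rise each, and housekeeping genes (-0.53, 0.299) had 2 and 3. Actb differed by -0.52 (adjusted p = 0.109) and Gapdh by -0.69 (0.0784).

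In total 3409 genes rose on the liver arrays and 3865 fell. All 7 liver arrays lay on 1 side of the in vitro array for 64.8% of genes, where chance gives 25%. Scaling to the median of the array moved the median of all genes from -0.25 to -0.54, and the counts became 2763 and 6352. Against the in vitro array alone, 3020 genes rose and 3211 fell in IRI (median of all genes -0.28), and 3577 rose and 3823 fell in non-IRI (-0.24); median scaling gave 2539 and 5546 (-0.58), and 2880 and 6082 (-0.54). Without IRI 3 the falls of IRI against culture numbered 1699. Within slide 1 alone, IRI against culture gave 2814 rises and 2415 falls, of which 2605 and 2103 were shared with the fit on 8 arrays. Past camera were 24 lists in IRI and 22 in non-IRI, and all of these calls were lost with an estimated correlation. Of the hepatocyte genes 19 rose and 1 fell in IRI (median 4.28, or 2.99 at the floor), and 7 rose and 2 fell in non-IRI (1.37, or 1.06). Both comparisons share the 1 in vitro array, which has no replicate, so its own variation is not measured.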

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

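The tests of slides, of RNA from hepatocytes or other host cells, and of the in vitro array's sensitivity were chosen after the results were seen; the tests of other probes and of other splits of the arrays were set before, apart from the count of probes far enough above the floor.

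Hepatocyte genes were higher on IRI arrays, with 17 of 29 risen. Against the signal of single probes, 8 other kept probes of 7 hepatocyte genes had a median log2 difference of 3.82. The probes used had 3.21. In non-IRI the other probes of Ahsg (-5.44) and Alb (-5.61 and -5.90) lay below the floor, so the size of the 3.82 is uncertain. Of 35 splits of the liver arrays, only the real one gave 17 risen members (highest other 0) or 76 rises (highest other 1). Every other split puts IRI and non-IRI arrays together in a group, which widens the spread. Few calls there were thus foreseeable and say little about chance. The split of non-IRI 1, 2 and 4 from the rest had a hepatocyte median of -2.72 and 0 called members. A larger share of hepatocyte RNA in the IRI samples stays open: that 28 of 29 genes were higher is the pattern itself and lends it no support. Alb was higher by 3.21 and Fabp1 by 5.22, while Tf (5.89 and 5.62), Rbp4 (1.12 and 0.75) and Fgg (0.19 and -0.30) stayed closer and Hpd differed by -0.93; single genes picked by their values decide neither way. The slides coincide with the groups, the labels describe no sort that would remove hepatocytes, and a response to injury in hepatocytes or ATSC was not tested.

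The 561 genes lower in IRI were mostly records without a symbol. For 93.8% of them the in vitro array, on the slide of the IRI arrays, lay below the non-IRI mean, against 40.7% of all genes. The falls were chosen for a high non-IRI mean, so this share alone decides nothing about the slides. The in vitro value lay nearer the IRI than the non-IRI mean for 76.5% of the falls, against 52.1% of all genes. Medians of the falls were -2.87 in IRI, -2.61 in vitro and -1.12 in non-IRI. That goes with a slide difference, but the in vitro group is 1 array of another condition and cannot decide it. Other kept probes of 12 fallen genes with a symbol had a median of -0.0043 where the probes used had -1.35. Only 4 of those 13 probes lay far enough above the floor to show such a fall. These 4 had a median of 0.31 against -1.16 for the probes used, and 1 of them was lower in IRI. That goes with a signal of single probes for these genes, but 4 probes are too few to decide it for the 561. Only the real split, 1 of 35, gave as many falls (highest other 1), and it is also the split by slide. The other splits mix IRI and non-IRI arrays, which widens their spread and holds their calls down. A difference between slides, a signal of single probes and an effect of injury therefore cannot be told apart here.

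Leukocyte, mesothelial, erythroid and hepatocyte genes were higher on liver arrays than in culture. Lower sensitivity of the in vitro array is argued against by the macrophage median of 8.66 with undetected values at the floor, and a slide difference by its 9.82 between the IRI and in vitro arrays of slide 1. RNA of host cells stays open: in 5 of 5 lists (macrophage, T and NK cell, erythroid, mesothelial, hepatocyte) most of the genes, or as many as not, rose, but this is the pattern itself. On the liver arrays Lyz2 stood at 8.55 and 8.59, Hbb-b1 at 6.44 and 5.58, Krt18 at 4.08 and 4.96, and Alb at 3.86 and 0.65 in IRI and non-IRI, and 3 of 21 macrophage genes are also complement genes. A change within ATSC as the only source is argued against by list means of unrelated cell types on the liver arrays themselves. In IRI and non-IRI these were 4.72 and 4.17 for macrophages, 4.16 and 4.68 for MHC class II, and 0.96 and 1.68 for mesothelium. T and NK cells had 0.15 and -0.14, and the mesenchymal stromal list 4.42 and 4.37. A change within ATSC beside host RNA stays open and was not tested, and the labels name no sort.

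For the number of lists past camera in IRI against non-IRI, 14 of 35 splits gave as many as the real 12 (highest other 18), so chance cannot be excluded for that count. Of the 8 splits that part all 3 same-number pairs, the real one called 637 genes and the others 0, and the splits that part fewer called at most 1. All splits but the real one mix IRI and non-IRI arrays, which holds their calls down. Since the numbers may pair the arrays, the comparison is with those 8, which are too few for a share under 0.05.

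Among the 4 non-IRI arrays, 7 of 188 values (3.72%) had 1 array far from the others, and chance gives about 1 in 20. The adipocyte list mean was 0.31 on non-IRI 2 and -0.68 to -0.60 on the others. The apoptosis and p53 list mean was 1.43 on non-IRI 3 and 1.22 to 1.25 on the others. Lactb was -1.69 on non-IRI 4 and -1.35 to -1.29 elsewhere. Kdr was 5.39 on non-IRI 4 and 3.98 to 4.10 elsewhere. Retn was 2.44 on non-IRI 3 and 0.98 to 1.22 elsewhere. Cd200 was 1.12 on non-IRI 3 and 1.82 to 1.92 elsewhere. The median coefficient of variation of replicated probes was 4.70% on non-IRI 4 and 3.96 to 4.07% on the others.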

How the results depend on the processing

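Normexp background correction, fits on genes with a symbol, the rule that a gene's probes agree, and the fit on slide 1 alone were added after seeing the data. The planned normexp on mean signals was not run, as the files hold no such column, and median signals were used. An offset of 50 was added, next to median processed signals of 13.0 (in vitro) to 25.9 (IRI 2). Such an offset shrinks log2 differences of dim genes. A slide term for IRI against non-IRI or non-IRI against culture, as fixed or random block, could not be fitted, and for IRI against culture it changes nothing by construction.

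For IRI against non-IRI, the 76 rises and 561 falls became 0 and 0 under normexp. There 17 spots had a background over 3 times the array's median (up to 67346.5 on non-IRI 4). With the background of those spots set to the array's median, the setting called without bright spots, there were 67 and 352. At an unadjusted p under 0.05 the limma count was 3184. Array weights gave 778 and 1637, the replicate block 19 and 209 (17 and 199 shared), a symbol filter 41 and 71, and detection on all 8 arrays 35 rises. Among the 2933 genes with several kept probes, 9 rises and 17 falls became 5 and 2 where a gene's probes agree. Leaving out 1 array gave 21 to 86 rises and 256 to 605 falls. Quantile normalization gave 92 and 591, the authors' values 73 and 595, and a 2-fold limit 66 and 501, with 0 genes called in the opposite direction. Orm1 turned to -0.081 under normexp (adjusted p = 0.94; 0.196 without the bright spots). The lists past the test numbered 12, and 22 under normexp, 6 with detection on all 8 arrays, 2 with fry, 0 with an estimated correlation and 7 to 15 without 1 array (7 without non-IRI 1).

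For liver against culture, the 3409 rises became 510 under normexp, 1773 without the bright spots, 1895 with detection on all 8 arrays and 1552 with symbols, and the 3865 falls 6352 with median scaling, 223 under normexp and 6285 with weights. In IRI against culture the 3020 rises became 475, 1597, 1653 and 1475 under the same settings, and the 3211 falls 5546, 159 and 6445, 1946 without a detection filter and 1699 to 3740 without 1 array (1699 without IRI 3). In non-IRI against culture the 3577 rises became 429, 1871, 2048 and 1493, and the 3823 falls 6082 with median scaling and 203 under normexp. With an estimated correlation 0 lists passed in each of these comparisons, against 23, 24 and 22, and 13 passed in IRI against culture with detection on all 8 arrays. The ribosomal median turned to 0.050 with quantile normalization. Symbol and detection filters test fewer genes, left-out arrays give fewer samples, and the normexp offset shrinks differences of dim genes. For the other settings the cause was not tested.

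Of 73 named genes in IRI against non-IRI, 73 kept direction and side of the threshold with quantile normalization and the authors' table, 70 with median scaling, 58 with the block (13 lost a call, 2 gained one), 60 under normexp without bright spots (6 lost, 7 gained) and 47 with them (25 lost, 1 turned). Of 84 in liver against culture, 79 did so with quantile normalization, 84 with median scaling and the authors' table, and 79 and 55 under normexp without and with bright spots. For named genes and list calls, the block changed none other than those given. Dim signals limit all of this: between 53.5% and 59.7% of spots were well above background.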

Other observations

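Growth factor genes moved both ways between liver and culture, with 7 risen and 18 fallen of 38. Among members named because of their values, Angptl4, an inhibitor of lipoprotein lipase, rose at least 312-fold on the liver arrays, and Igf1, which liver and macrophages secrete, rose by 4.18. Among proteases, the macrophage enzymes Mmp9 and Mmp12 rose at least 34.6-fold and 42.5-fold. Bcl2a1, a survival factor of leukocytes, rose at least 46.9-fold, and Col8a1, a short-chain collagen, fell by 2.79.

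The cytokine and chemokine list as a whole differed by a median of 0.12 between IRI and non-IRI, with 21 of 33 genes higher and camera at 0.0965. Among members named because of their values, Il1b stood at 5.18 ± 0.88 (SD, n = 3) in IRI and 3.06 ± 0.72 (n = 4) in non-IRI (limma adjusted p = 0.0748), and Tnf at -3.17 ± 1.34 in IRI and not well above background in non-IRI (0.114). Irf1, an interferon-induced factor, stood at 0.58 and -0.36 (0.216), and Birc3, an inhibitor of apoptosis, at 1.82 and 0.94 (0.155). Mdm2, a p53 target, stood at 1.25 ± 0.12 in IRI and 1.83 ± 0.12 in non-IRI (0.103). RT1-Bb was lower in IRI by -1.40 at the probe used, and another kept probe of it differed by 2.88.

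The first principal component of all 8 arrays held 61.7% of the variance and set the in vitro array (221.5) apart from the liver arrays (-40.8 to -22.1). Over the 7 liver arrays it held 35.6%, and non-IRI 3 (-2.46) lay closest to the IRI arrays (-52.1 to -34.2).

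Falls in IRI made up 9.51% of genes represented by predicted RefSeq records, 5.88% of Ensembl transcripts and 1.02% of curated RefSeq messages. Of 2933 genes with more than 1 kept probe, 5 rose and 2 fell with agreeing probes.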
